A study of Mus musculus with 24 samples.

How the data were processed

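Messenger RNA of mouse fibroblast lines was measured on 24 Affymetrix-type oligonucleotide arrays in 12 groups of 2 arrays. In the first 12 arrays, called the tunicamycin arrays here, wild-type, ATF4-/- and PERK-/- cells were untreated or treated with 2 ug/ml tunicamycin. The labels give 6 h for wild-type and ATF4-/- cells and no duration for PERK-/- cells. In the other 12, called the Fv2E-PERK arrays here, cells expressing the drug-activated kinase Fv2E-PERK were untreated or treated with AP20187 for 4 h or 8 h, at a dose the labels write as 2 nm. These cells carried wild-type eIF2alpha in a PERK-/- background (the SS line) or mutant eIF2alpha (the AA line). The labels do not state whether the AA line also has a PERK-/- background. Groups were taken from the submitters' sample descriptions and titles. The running numbers in a few descriptions differ from those in the titles, while group and replicate read the same in both.

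The table the authors deposited holds 12488 probe sets, and its values behave as a linear ratio of each probe set to its own median over the 24 arrays. This was read from the values, since the median was 1 within 0.01 for 91.51% of probe sets. The image analysis, summarisation and scaling behind the table are not given in the sources used here, so the original brightness scale and the centring of each array stay unknown. No signal over background could be given, and the number of arrays limits the precision. The lowest value in the table is 0.01, called the floor here. It made up 22.6% to 25.6% of the values on each tunicamycin array and 0.00805% to 0.105% on each Fv2E-PERK array. The median ratio was 0.796 and 0.716 on the untreated wild-type arrays, 0.754 and 0.779 on the tunicamycin-treated ones, 0.778 and 0.795 on untreated ATF4-/-, 0.854 and 0.819 on treated ATF4-/-, 0.749 and 0.775 on untreated PERK-/-, and 0.748 and 0.756 on treated PERK-/- arrays. It was 1.11 and 1.17 on untreated SS, 1.10 and 1.12 on SS 4 h, 1.16 and 1.22 on SS 8 h, 1.18 and 1.19 on untreated AA, 1.19 and 1.18 on AA 4 h, and 1.19 and 1.17 on AA 8 h arrays. Levels were therefore not compared between the tunicamycin arrays and the Fv2E-PERK arrays, and every comparison lies within one of these sets. Because every value is relative to its probe set's own median, the level of one gene cannot be set against that of another.

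After 66 control probe sets (AFFX) were left out, 12422 remained. A probe set was tested where it was never at the floor on any of the 24 arrays, which left 7369. Of the remainder, 1351 were at the floor on all 12 tunicamycin arrays and 3684 on 1 to 11 of them. Ratios were used on the deposited scale as log2(ratio + 0.247), the pseudocount being the median of all values divided by 4. limma (version 3.58.1, in R 4.3.3, with the package data.table at version 1.17.8) fitted the means of the 12 groups to all 24 arrays with 12 residual degrees of freedom and a trended prior. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over the 7369 probe sets and a threshold of 0.05. A difference of responses between 2 lines is an interaction contrast of the same fit. The labels do not say that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

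Fold values in the text are ratios of group means of the deposited ratios, while log2 changes, with standard errors, are on the log2(ratio + 0.247) scale, which understates the change of low values. Folds are rough where a group mean lies under the pseudocount. Gene names came from the platform annotation, in which 10833 of the 12422 probe sets had 1 symbol, 396 several and 1193 none. Of the 10833, 10817 were matched by Entrez ID to a RefSeq gene table (mouse genome version 38, used for names only), and 0 symbols changed. For each gene the probe set with the fewest floor values was used, then the one with a plain suffix, then the lowest number. Of 263 calls of named genes 53 had another tested probe set. In 25 of these every other probe set was called the same way, in 28 some were not, and in 8 some had the opposite sign, with 0 called the opposite way.

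The contrasts, the tests, 26 gene lists and the rule for the genes named in the text were fixed before the data were examined, together with most of the alternative settings. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among called probe sets of exactly 1 gene whose 2 arrays in one group both lay above both arrays of the other. For a difference of responses this held in the line with the larger response. It also took Atf4, Eif2ak3, Eif2s1, Ddit3, Atf3, Trib3, Chac1, Asns, Ppp1r15a, Hspa5, Dnajb9 and Herpud1 in every comparison, and up to 4 members with the smallest p of each gene list described, with members that went against the others. The lists covered integrated stress response genes, amino acid transporters, tRNA synthetases, amino acid synthesis, ER chaperones, ER-associated degradation, NRF2 targets, cholesterol and fatty acid synthesis, p53 targets, heat shock, cell cycle, ribosomal proteins, extracellular matrix, NF-kB targets, immediate early genes, interferon response, glycolysis, and markers of fibroblasts, smooth muscle and other cell types. They held 627 entries, of which 492 were on the array and 370 had a tested probe set. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 26 lists within a comparison. Of 92 calls at the preset correlation, 24 held with an estimated one.

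3 parts of the processing depart from what had been fixed, because the table held ratios to each probe set's own median rather than intensities. The plan asked for quantile normalization where trimmed array means (2% trim) deviated from their mean by over 5%. They deviated by up to 37.9%, but blocks of floor values on one set of arrays make whole distributions unlike, so the deposited scale was kept. The probe sets tested were never at the floor, however, so this reason does not cover them. Their median log2 ratio was 0.00783 and 0.0203 on the SS 4 h arrays and 0.0726 and 0.180 on the SS 8 h arrays. Such array-wide shifts were left in place, and only the settings with quantile normalization remove them. The planned filter, a value above the overall median on at least 2 arrays, would have left out only 23 probe sets. It was replaced by the floor filter, and the planned choice of the probe set with the highest mean by the floor rule above. These choices were made after counts of calls under 15 settings had been seen. For tunicamycin in wild-type cells the processing as planned called 86 probe sets, 43 of them among the 207 reported here, the planned filter alone called 285, and a fit of the tunicamycin arrays alone called 62, of which 58 were among the 207.

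The fit was tested on simulated data with the spread of each set of arrays and 200 changed probe sets in each of 10 draws. For tunicamycin in wild-type cells it recovered 62.8% of log2 changes of 1 and 96.2% of changes of 2, and 18.3% of its calls were false, against 5.33% with the tunicamycin arrays fitted alone, which recovered 35.9% and 88.4%. The reason is that the spread was pooled over sets of arrays of unlike noise, with a median residual SD of 0.249 on the tunicamycin and 0.199 on the Fv2E-PERK arrays. The false share was 19.3% for the ATF4-/- minus wild-type and 18.5% for the PERK-/- minus wild-type response, where 27.8% and 25.3% of changes of 1 were recovered. For AP20187 at 8 h in SS it was 2.76%, with 59.8% and 95.3% of changes of 1 and 2 recovered, and for AA minus SS at 8 h 3.54%, with 20.1% and 83.4%. With no change simulated, the mean number of calls was 1.97 on the tunicamycin and 0.0625 on the Fv2E-PERK arrays. A simulated shift of 0.5 in a list of 21 genes was found by camera, and 0 of 25 other lists were called. These simulations drew each probe set independently, with the same spread for all groups of a set and no deviation shared across an array. The real groups were unlike, with a correlation of 0.675 between the AA 8 h arrays and 0.932 between the SS 8 h arrays. The false shares may therefore be too low for these data.

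The alternatives tried were quantile normalization, over all arrays or within each set; 4-fold smaller and larger pseudocounts; no filter, the planned filter and a filter at the 75th percentile; no trend in the prior; a fit of only the groups compared; the replicate number as a block; the probe set with the highest mean or variance per gene; the processing as planned; each set of arrays alone; the fit without the second AA 8 h array; and each array left out in turn. The processing as planned, the planned filter, the separate sets, quantile normalization within each set and the fit without that AA array were added after seeing the data, as was the use of the highest-mean rule as an alternative. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Genomic positions and probe sequences were not analysed here.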

Results

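Gene expression was measured in 5 mouse fibroblast lines that differ in the integrated stress response, the pathway in which the ER stress sensor PERK (gene Eif2ak3) phosphorylates the translation factor eIF2alpha and thereby raises synthesis of the transcription factor ATF4. Tunicamycin blocks N-linked glycosylation and causes ER stress. Wild-type, ATF4-/- and PERK-/- cells had 2 untreated and 2 tunicamycin-treated arrays each. Fv2E-PERK is a chimera whose kinase part is switched on by the dimerizer AP20187 without ER stress. The SS line, with wild-type eIF2alpha in a PERK-/- background, and the AA line, with mutant eIF2alpha and no stated PERK background, had 2 arrays each for untreated cells, 4 h and 8 h of AP20187. Over the 7369 probe sets tested, the 2 arrays of a group correlated with r = 0.711 to 0.785 on the tunicamycin arrays and 0.675 to 0.932 on the Fv2E-PERK arrays, the lowest being AA at 8 h.

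The disrupted genes were read first. Atf4 had ratios of 0.170 and 0.133 in untreated and 0.166 and 0.153 in tunicamycin-treated ATF4-/- cells, against 0.769 and 0.745 in untreated and 1.64 and 1.62 in treated wild-type cells. In PERK-/- cells it was 0.573 and 0.383 untreated, and 1.03 and 0.783 treated. In SS it was 1.38 and 1.54 untreated, 2.61 and 2.84 at 4 h, and 2.89 and 3.67 at 8 h. In AA it was 0.800 and 0.908 untreated, 1.03 and 0.996 at 4 h, and 1.004 and 1.088 at 8 h. Atf4 was lower in untreated ATF4-/- than in untreated wild-type cells by -1.33 ± 0.15 (log2, SE; limma adjusted p = 0.000471). Eif2ak3 was 0.398 and 0.241 in untreated and 0.987 and 0.556 in treated PERK-/- cells. This gene was 1.91 and 0.0222 in untreated and 2.26 and 1.97 in treated wild-type cells, and 0.871, 1.01, 1.44 and 1.61 in ATF4-/- cells. In SS its ratios were 0.791 and 0.466 untreated, 0.922 and 0.691 at 4 h, and 0.527 and 0.603 at 8 h. In AA they were 1.61 and 1.197, then 1.68 and 1.52, then 1.26 and 1.48. Whether the probe sets of Atf4 and Eif2ak3 lie in the deleted part of each gene is unknown. The Atf4 signal left in ATF4-/- cells is therefore not a measure of intact transcript, and Eif2ak3 checks nothing about the PERK-/- label. Eif2ak3 passed limma's test in 0 of the 15 comparisons. Eif2s1, which encodes eIF2alpha, and Chac1 had no probe set.

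**Figure D1:**
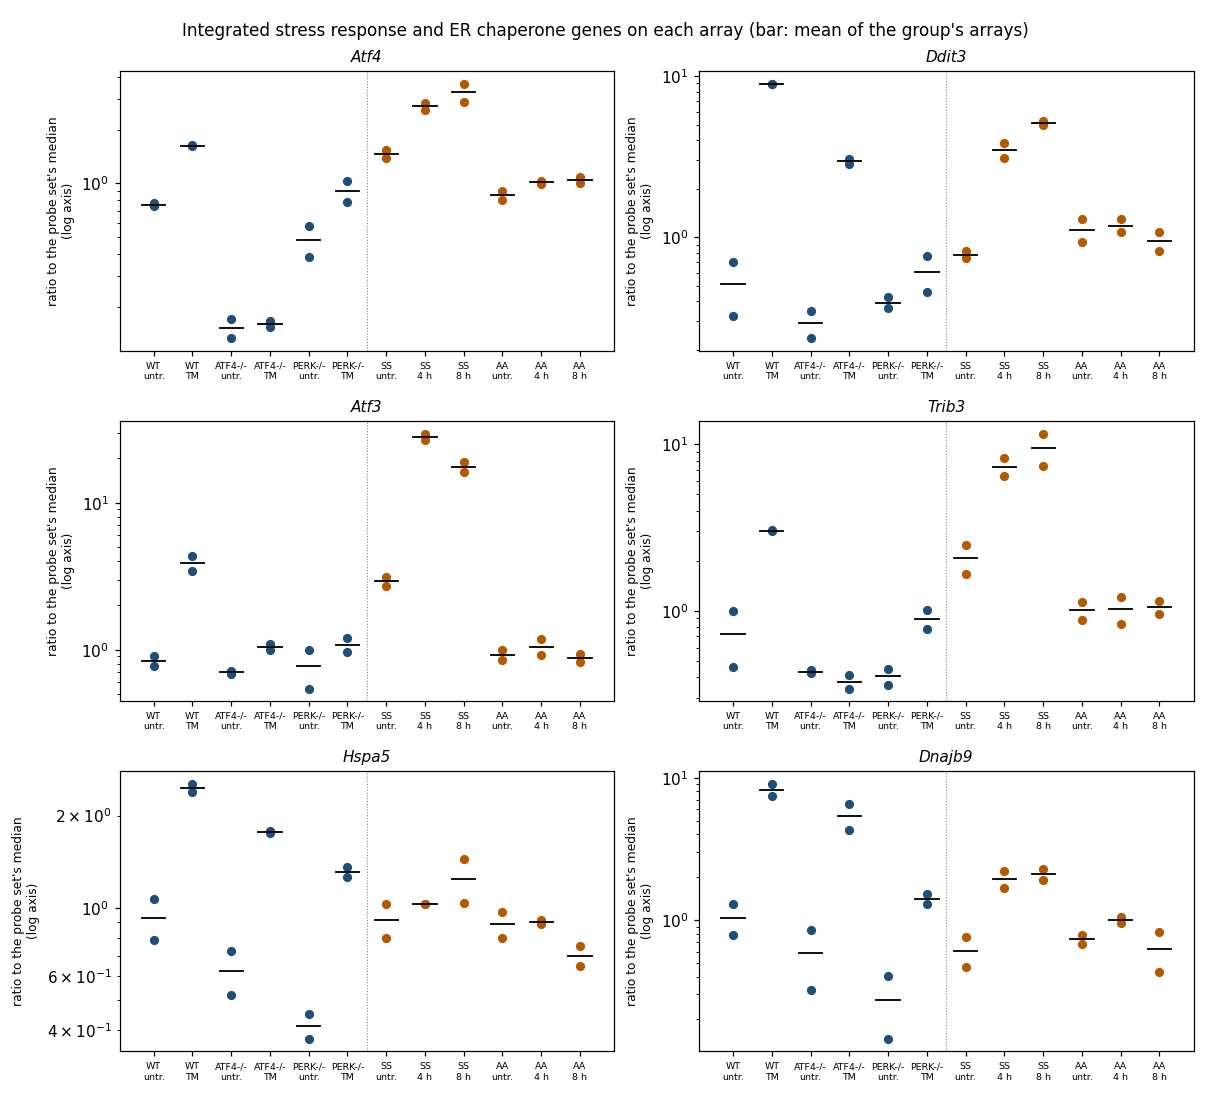
Ratio of 6 genes to their probe set's own median over the 24 arrays (log axis), for each array (points) and as the group mean (bars), by line and treatment. The wild-type mean of Ddit3 went from 0.514 untreated to 8.96 with tunicamycin (TM), and that of Atf4 in ATF4-/- cells was 0.152 and 0.160.

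The first comparison asked which genes tunicamycin changed in wild-type cells. Ddit3 encodes the stress transcription factor CHOP. It rose 17.4-fold, from a ratio of 0.514 ± 0.270 to 8.96 ± 0.0562 (SD, n = 2 arrays each). The co-chaperone Dnajb9 rose 7.90-fold, the ER membrane protein Herpud1 8.62-fold, the ER-resident Creld2 8.46-fold, and the degradation adaptor Sel1l 4.87-fold. Rises were also seen in the oxidase Ero1b (4.44-fold) and the secreted ER factor Manf (4.59-fold). Atf4 itself rose 2.15-fold, Atf3, a stress-induced transcription factor, 4.61-fold, Trib3, a pseudokinase downstream of ATF4, 4.19-fold, and the chaperone BiP (Hspa5) 2.65-fold. Further large rises were in Gtpbp2, Gch1, the first enzyme of tetrahydrobiopterin synthesis, and Ptx3, a secreted pentraxin (8.15, 5.35 and 4.39-fold). The largest falls were in Mc1r, the melanocortin receptor (-2.14 ± 0.25, log2, SE), Tsks (-2.03 ± 0.46), S100a4 (-1.98 ± 0.38), Gpr37l1 (-1.93 ± 0.48), Gp9 (-1.78 ± 0.31) and Ak1 (-1.62 ± 0.28). Next came Ramp1 (-1.62 ± 0.35), Cct2 (-1.59 ± 0.31), Dhcr7, a late enzyme of cholesterol synthesis (-1.59 ± 0.33), and Slc4a3 (-1.48 ± 0.36). Asns, asparagine synthetase, was 1.77-fold higher without passing the test (limma adjusted p = 0.0771), and so was Eif2ak3 (0.187). The other tested probe set of Atf3 was at 0.37 ± 0.33 (0.735), so the rise of Atf3 rests on 1 of 2 probe sets.

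Lists of integrated stress response and ER chaperone genes were higher by both forms of camera. 11 of 17 tested integrated stress response genes were higher and 0 lower (15 and 0 adjusted over the list alone), with a list median of 1.01 and a camera adjusted p of 7.87e-20. ER chaperones and folding enzymes gave 11 higher of 21 (12 adjusted over the list alone, median 0.92, camera adjusted p = 7.87e-20). Both calls held with an estimated correlation (adjusted p = 0.00149 for each). The calls of lists of amino acid supply and ER-associated degradation did not. The tRNA synthetases, which charge tRNAs with amino acids, had 6 of 16 higher (9 adjusted over the list alone, camera adjusted p = 4.87e-10, adjusted p = 0.0609 with an estimated correlation), among them Wars (1.07 ± 0.17) and Aars (0.90 ± 0.14). Of 38 genes of ER-associated degradation and trafficking 9 were higher (14 adjusted over the list alone, camera adjusted p = 6.66e-09, adjusted p = 0.0747 with an estimated correlation), with Edem1 and Derl1 at 1.74 and 0.99. Amino acid synthesis had 3 of 14 higher (7 adjusted over the list alone, camera adjusted p = 0.000243) and amino acid transporters 3 of 7 (3, with 1 lower, adjusted over the list alone; camera adjusted p = 0.0063). Each of these had an adjusted p = 0.0747 with an estimated correlation. Slc3a2 and Slc7a5, the chains of one transporter, rose by 1.43 and 1.05, while Slc38a4 was at -0.61 without passing the test over all probe sets.

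Lists of cholesterol and fatty acid synthesis, extracellular matrix and fibroblast markers were called lower by camera at the preset correlation only. Of 19 lipid synthesis genes 3 were lower (3 adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.341 with an estimated correlation): Idi1 (-1.24), Dhcr7 and Scd2 (-0.87). Of 33 matrix genes 3 were lower (4 adjusted over the list alone, camera adjusted p = 0.000182, adjusted p = 0.0609 with an estimated correlation), namely Timp2 (-1.02), Col3a1 (-1.10) and Nid1 (-0.95). The fibroblast markers, which share members with the matrix list, had 2 of 10 lower (4 adjusted over the list alone, camera adjusted p = 0.000432, adjusted p = 0.0571 with an estimated correlation). In all, limma called 207 probe sets, 151 higher and 56 lower. Fitting the tunicamycin arrays alone called 62, with Ddit3, Creld2, Dnajb9, Herpud1, Ptx3, Sel1l, Ero1b, Manf, Mc1r, Dhcr7, Atf3, Trib3 and Hspa5 still called. In simulations 18.3% of the calls of the fit used here were false. The processing as planned called 86, no filter 284 (178 higher), the planned filter 285 (179 higher), and a fit of only these groups 0. Leaving out the first or second untreated array gave 176 (151 higher, 25 lower) or 117 (88 and 29), and the first or second treated array 123 (83 and 40) or 127 (68 and 59). Of these 122, 80, 97 and 87 were among the 207.

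The same question in ATF4-/- cells shows which responses occurred in a line without ATF4. ER genes rose with Dnajb9 9.18-fold, Creld2 8.00-fold, Manf 6.02-fold, Ero1b 3.79-fold, Hspa5 2.84-fold and Dnajc3, an ER co-chaperone, 5.19-fold. Herpud1 rose by 2.19 (log2). Ddit3 rose 10.1-fold, from 0.292 ± 0.0797 to 2.95 ± 0.141 (SD, n = 2 each). Gadd45b, a growth arrest and DNA damage gene, rose 5.67-fold, the NF-kB subunit gene Relb 5.75-fold, and the noncoding RNA Snhg5 4.03-fold. Atf4 (0.03 ± 0.15, log2), Atf3 (0.45 ± 0.35), Trib3 (-0.13 ± 0.28), Asns (0.01 ± 0.19) and Eif2ak3 (0.58 ± 0.58) did not pass the test, with limma adjusted p of 0.975, 0.686, 0.925, 0.992 and 0.784. Falls were largest in the retinaldehyde dehydrogenase Aldh1a1 (-2.88 ± 0.58, though its other probe set gave 0.96), Il6ra (-2.37), Cyp2b10 (-2.27), Adgra3 (-2.08), Gp5 (-1.49), Gp9 (-1.44), Myrf (-1.29), the myosin light chain Myl9 (-1.22), St3gal3 (-1.06) and Tmsb4x (-0.86). The calls of Aldh1a1, Il6ra, Cyp2b10, Gp5 and Gp9 were lost with any of the 4 arrays left out. Il6ra and Cyp2b10 were each called in 8 of 14 settings.

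ER chaperones had 9 of 21 higher in ATF4-/- cells (14 adjusted over the list alone, median 0.85, camera adjusted p = 5.62e-20, adjusted p = 0.002 with an estimated correlation). ER-associated degradation had 4 of 38 higher (13 adjusted over the list alone, camera adjusted p = 1.19e-11, adjusted p = 0.0614 with an estimated correlation), with Selenos at 1.55, Sel1l at 1.39 and Xbp1 at 1.195. Several lists had lower medians with few or no members called. Matrix genes had a median of -0.36, with 0 of 33 called and 1 adjusted over the list alone (camera adjusted p = 3.21e-06, adjusted p = 0.0418 with an estimated correlation). Lipid synthesis had 0 called and 2 lower adjusted over the list alone (median -0.31, camera adjusted p = 0.000564), and fibroblast markers 0 and 3 (median -0.46, 0.000724). Smooth muscle markers had 1 of 7 lower and 1 adjusted over the list alone (Myl9; camera adjusted p = 0.013), glycolysis genes 0 of 15 and 0 (median -0.22, 0.0239), and NRF2 targets 0 of 18 called with 1 higher and 1 lower adjusted over the list alone (median -0.20, 0.0452). With an estimated correlation those 5 had adjusted p = 0.277, 0.0613, 0.112, 0.381 and 0.381, in that order. limma called 85 probe sets in ATF4-/- cells, 65 higher and 20 lower, and quantile normalization 200 (124 higher, 76 lower) or 181 within each set of arrays. The tunicamycin arrays alone gave 31 (29 higher), still including Dnajb9, Ddit3, Creld2, Herpud1, Manf, Dnajc3, Snhg5, Relb, Cyp2b10, Gp5 and Hspa5. Only these groups gave 0, and leaving out the first or second treated array gave 37 or 45.

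In PERK-/- cells, whose treatment time is not stated, tunicamycin raised the ER chaperones Hspa5 3.18-fold and Hsp90b1 2.52-fold, the disulfide isomerase P4hb 3.29-fold and the transporter chain Slc3a2 3.31-fold. The metalloprotease gene Mep1b rose 8.10-fold, and Arih1 rose by 1.43 (log2), although the probe set of Arih1 with the highest mean gave -0.14. Tm4sf1 fell by 1.66 (its other probe set gave 0.04), the chromatin protein gene Hmga2 by 1.43, the basement membrane gene Nid1 by 1.23, Serpinf2 by 1.15, Hps1 by 0.96 (-0.05 by its other probe set) and Tmem131 by 0.93. Ddit3 went from 0.392 ± 0.0427 to 0.611 ± 0.216 (SD, n = 2 each) without passing limma's test (adjusted p = 0.7003). The same held for Atf4 (0.67 ± 0.15, log2), Atf3 (0.41 ± 0.35), Trib3 (0.81 ± 0.28), Asns (0.73 ± 0.19), Dnajb9 (1.71 ± 0.34, 0.0554), Herpud1 (1.23 ± 0.28) and Eif2ak3 (0.83 ± 0.58).

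ER chaperones as a list were higher in PERK-/- cells, with 3 of 21 called (7 adjusted over the list alone, median 0.43, camera adjusted p = 4.93e-14, adjusted p = 0.00953 with an estimated correlation). ER-associated degradation had 0 of 38 called and 9 higher adjusted over the list alone (camera adjusted p = 1.34e-11), and integrated stress response genes 0 of 17 and 5 (median 0.40, 8.87e-06). Lipid synthesis had 0 of 19 called and 5 higher adjusted over the list alone (median 0.46, 7.24e-08), with 18 of 19 above 0. Amino acid transporters had 1 of 7 higher and 2 adjusted over the list alone (0.00032), and amino acid synthesis 0 of 14 and 3 (0.00106). With an estimated correlation these 5 had adjusted p = 0.0829, 0.0904, 0.0907, 0.0675 and 0.134. Immediate early genes had 0 of 16 called and 6 lower adjusted over the list alone (median -0.36, camera adjusted p = 0.000693, adjusted p = 0.271 with an estimated correlation). limma called 17 probe sets, 7 higher and 10 lower. The count was 0 with the tunicamycin arrays alone and 0 with only these groups, 10 as planned, 9 (5 higher) with quantile normalization within each set, 33 (22 higher, 11 lower) with quantile normalization, 40 with the smaller pseudocount, and 69 with no filter or the planned filter. The split turned with the array left out: 20 (16 higher, 4 lower) and 37 (28 and 9) without the first and second untreated array, 89 (25 and 64) and 37 (12 and 25) without the first and second treated one.

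Whether the knockouts responded differently from wild type was tested as a difference of responses. Each genotype is a single line, so a difference can belong to the knockout or to the line. For ATF4-/- minus wild type, integrated stress response genes had a list median of -0.87, with 0 of 17 called over all probe sets and 13 lower adjusted over the list alone (camera adjusted p = 2.38e-15, adjusted p = 0.00856 with an estimated correlation). This list includes Atf4, the disrupted gene, whose own difference is the list median, and the list was not tested without it. Ppp1r15a is also on the list, but the floor filter left it out. With the planned filter the difference of Ppp1r15a was -3.53 ± 0.43 (limma adjusted p = 0.00241), with 1 untreated wild-type array at the floor. Trib3 was at -1.94 ± 0.40 (limma adjusted p = 0.121), Atf4 at -0.87 ± 0.22 (0.199), Atf3 at -1.47 ± 0.49 (0.431), Ddit3 at -1.06 ± 0.35 (0.423), Asns at -0.66 ± 0.27 (0.600), Herpud1 at -0.55 ± 0.40 (0.944) and Eif2ak3 at -1.05 ± 0.82 (0.970). The sign for Herpud1 depends on the pseudocount, because its untreated ATF4-/- ratio was only 0.0902: by group means, a rough figure at so low a ratio, it rose more in ATF4-/- (14.0-fold) than in wild type (8.62-fold), and with the smaller pseudocount the difference was 0.10. For the chaperones Hspa5 and Dnajb9 the differences were 0.01 ± 0.24 and 0.06 ± 0.48. The tRNA synthetases (median -0.33, 0 called, 4 lower adjusted over the list alone, camera adjusted p = 3.86e-05), amino acid synthesis (-0.38, 0 and 2, 0.00161) and transporters (-0.63, 0 and 0, 0.0159) were lower as lists, with adjusted p = 0.291, 0.230 and 0.230 with an estimated correlation. 4 probe sets were called, 2 higher and 2 lower, of which the naming rule took Gadd45b (2.60 ± 0.38, though 1.35 and not called by its other probe set), Mc1r (2.26 ± 0.35) and St3gal3 (-2.10 ± 0.24). Gadd45b was 5.67-fold its untreated level in ATF4-/- and 0.416-fold in wild type. The fourth, named after its values were seen, was Lonp1, a mitochondrial protease gene, which changed by 2.16 in wild type and -0.12 in ATF4-/- (difference -2.275 ± 0.38, limma adjusted p = 0.039). Its other probe set gave a difference of 0.50 ± 0.43 (0.987). With no change simulated, this comparison gave 2 calls on average and up to 8 under the floor filter. The 4 calls do not exceed that. Under the planned filter, unchanged data gave 10.8 calls on average and up to 20, against 37 in the real data. The tunicamycin arrays alone and only these groups each gave 0 calls, and other settings 3 to 9, or 36 and 37 with no filter and the planned filter. Without single arrays the count was 22 and 20 (first and second untreated wild type), 8 (second treated wild type), 8 and 14 (untreated ATF4-/-) and 2 (first treated ATF4-/-), with the split going from 4 higher and 18 lower to 11 and 3. The simulated share of false calls was 19.3%.

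For PERK-/- minus wild type, Ddit3 responded less (-3.24 ± 0.35, limma adjusted p = 0.000775), as did Creld2 (-1.80 ± 0.25; 2.32-fold against 8.46-fold), the ER stress transcription factor Atf6 (-2.26), Myc (-1.94) and the ubiquitin ligase Siah2 (-2.21). The response was also lower for Hoxa4 (-2.20), Tnnt2 (-2.37), Rbpj (-1.62), Gnpnat1 (-1.58) and Stbd1 (-1.52), though the other probe set of Hoxa4 gave -0.04. Responses were higher in PERK-/- cells for Mep1b (3.96 ± 0.69), Mc1r (2.88), Gpr162 (1.91), the heat shock gene Hspa1b (1.82), Itgav (1.57; 0.07 and 0.0042 by its other probe sets) and Nudcd3 (1.49), and for 3 lipid synthesis genes: Dhcr7 (2.42 ± 0.46), Idi1 (1.64) and Scd2 (1.49). Hspa5 (0.03 ± 0.24), Dnajb9 (-1.03 ± 0.48), Herpud1 (-1.505 ± 0.40), Trib3 (-1.003 ± 0.40), Atf3 (-1.502 ± 0.49), Atf4 (-0.23 ± 0.22), Asns (0.06 ± 0.27) and Eif2ak3 (-0.81 ± 0.82, but 2.41-fold against 2.19-fold by group means) did not pass the test.

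Lipid synthesis had 3 of 19 members with a higher response in PERK-/- than in wild type (4 adjusted over the list alone), all 19 above 0, and a median of 0.60 (camera adjusted p = 5.65e-10, adjusted p = 0.0658 with an estimated correlation). Integrated stress response genes had 1 of 17 lower (6 adjusted over the list alone, median -0.74, camera adjusted p = 1.60e-07) and fibroblast markers 0 of 10 called with 3 higher adjusted over the list alone (0.000661); with an estimated correlation both also had an adjusted p = 0.0658. ER chaperones had 1 of 21 lower and 5 adjusted over the list alone (0.00129), tRNA synthetases 0 of 16 and 1 (9.34e-05), and immediate early genes 1 of 16 and 1 (0.00148). Matrix genes had 0 of 33 called and 2 higher adjusted over the list alone (0.0148). These 4 each had an adjusted p = 0.284 with an estimated correlation. limma called 34 probe sets, 12 higher and 22 lower, and 57 with no filter or the planned filter. The tunicamycin arrays alone and only these groups gave 0 each, and 18.5% of simulated calls were false. Leaving out 1 array gave 54, 21 and 18 (first and second untreated and first treated wild type) and 55, 72 and 16 (second untreated, first and second treated PERK-/-), with Ddit3, Mc1r, Atf6 and Creld2 called each time. The split ranged from 6 higher and 48 lower without the first untreated wild-type array to 18 and 14 without the second treated one.

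The Fv2E-PERK arrays asked what PERK signalling did without ER stress. After 4 h of AP20187 in SS, the immediate early transcription factor Fos rose 19.6-fold, Atf3 rose 9.63-fold from 2.92 ± 0.301 to 28.1 ± 1.85 (SD, n = 2 each), and Egr1, another immediate early factor, 7.25-fold. The other probe set of Fos was at 0.20 ± 0.56 (log2), while that of Atf3 also rose (2.42 ± 0.33). The chemokine gene Cxcl2 rose 9.45-fold, the linker histone gene H1f2 12.7-fold, and the synaptic scaffold gene Homer1 12.1-fold. Cyclin G2 (Ccng2) rose 7.38-fold, the kinases Clk4 and Grk5 5.82 and 5.44-fold, and Gch1 4.23-fold. Ddit3 rose 4.45-fold, Trib3 3.55-fold, Atf4 1.86-fold, Asns 1.81-fold (log2 0.73, and 1.92 by its other probe set), Herpud1 3.98-fold and Dnajb9 3.20-fold. The 4 h call of Asns was lost with any of the 4 arrays left out. The other probe set of Dnajb9 was at 0.75 ± 0.28 (log2) and was not called (limma adjusted p = 0.11). Hspa5 (0.14 ± 0.17, log2) and Eif2ak3 (0.28 ± 0.58) did not pass the test. Falls were largest in S100a4 (-1.94), the potassium channel gene Kcnk2 (-1.74), Trappc1 (-1.70), Ak1 (-1.67), Tnnt2 (-1.61), Mea1 (-1.57; -0.15 and -0.09 by its other probe sets), Anxa8 (-1.52), C1d (-1.47), Ggct (-1.44) and the matrix glycoprotein gene Sparc (-1.44 ± 0.19).

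Integrated stress response genes at 4 h had 12 of 17 higher (15 adjusted over the list alone, median 1.19, camera adjusted p = 5.23e-15, adjusted p = 0.00941 with an estimated correlation). Matrix genes had 6 of 33 lower (13 adjusted over the list alone, camera adjusted p = 2.44e-06, adjusted p = 0.0391 with an estimated correlation), with Sparc, Col3a1 (-1.25), Col6a2 (-0.99) and Col1a2 (-0.87). Immediate early genes had 7 of 16 higher and 9 adjusted over the list alone (camera adjusted p = 7.52e-07), tRNA synthetases 5 of 16 and 6 (0.000423), NF-kB targets 3 of 14 and 3 (0.0339; Cxcl2, Relb at 1.69 and Nfkb2 at 0.93) and interferon response genes 2 of 10 and 5 (0.00588; Irf1 at 0.74 and Tap1 at 1.10). Their adjusted p = 0.133, 0.335, 0.144 and 0.361 with an estimated correlation, in that order. ER-associated degradation was lower as a list (median -0.27, camera adjusted p = 0.00589, adjusted p = 0.385 with an estimated correlation) with members both ways: 2 of 38 higher, Xbp1 (1.24) and Herpud1, and 3 lower, including the translocon subunit Sec61b (-0.96) and Dad1 (-0.95), or 2 and 5 adjusted over the list alone. limma called 662 probe sets, 380 higher and 282 lower, and 1007 as planned. Leaving out the first untreated array gave 465 and turned the split (200 higher, 265 lower). Without the second untreated it was 256 (178 and 78), and without the first and second treated 182 (119 and 63) and 244 (160 and 84).

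At 8 h in SS, Ddit3 was 6.52-fold above untreated cells, Atf3 5.98-fold, Trib3 4.58-fold, Asns 2.36-fold (log2 1.07, and 2.90 by its other probe set) and Atf4 2.24-fold, from 1.46 ± 0.114 to 3.28 ± 0.555 (SD, n = 2 each). Fos and Egr1 stood at 8.09 and 5.57-fold. B4galnt2 rose 13.6-fold, Madcam1 8.65-fold, the calcium channel gene Itpr2 7.88-fold, Gch1 7.08-fold, Acbd6 6.27-fold, Vldlr, a lipoprotein receptor gene, 5.496-fold, Dnajb9 3.45-fold and Herpud1 2.90-fold. The other probe sets of Fos (0.29 ± 0.56, log2) and Vldlr (1.32 ± 0.50) were not called. Hspa5 (0.35 ± 0.17) and Eif2ak3 (-0.09 ± 0.58) did not pass. The chemokine genes Ccl7 and Ccl2 fell (-3.50 ± 0.49 and -2.29 ± 0.45), as did Tgfbi (-2.67), the proteoglycan gene Ogn (-2.28), the hyaluronan synthase gene Has2 (-2.27), Nrp1 (-2.22), S100a4 (-2.20), Ak1 (-2.10), the collagen gene Col3a1 (-2.06 ± 0.27) and Gstm2 (-2.03; -0.38 by its other probe set).

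The integrated stress response list had 14 of 17 higher at 8 h (15 adjusted over the list alone, median 1.38, camera adjusted p = 2.02e-13, adjusted p = 0.00746 with an estimated correlation), with Ero1a at 1.82 and Cebpg at 1.46. Cytosolic tRNA synthetases had 13 of 16 higher (15 adjusted over the list alone, median 0.99, camera adjusted p = 1.74e-12, adjusted p = 0.0371 with an estimated correlation): Lars 1.56, Eprs 1.17, Aars 1.08 and Iars 1.02. Amino acid synthesis had 4 of 14 higher (6 adjusted over the list alone, camera adjusted p = 0.00378, adjusted p = 0.166 with an estimated correlation), with Psph 1.31, Aldh18a1 1.11 and Mthfd2 0.72. Matrix genes had 11 of 33 lower (15 adjusted over the list alone, camera adjusted p = 1.16e-11, adjusted p = 0.00657 with an estimated correlation), with Sparc -1.75, Col1a2 -1.64 and Col1a1 -1.25. Fibroblast markers had 5 of 10 lower (5 adjusted over the list alone, camera adjusted p = 5.47e-06, adjusted p = 0.0108 with an estimated correlation). Lipid synthesis had 7 of 19 lower and 7 adjusted over the list alone (camera adjusted p = 4.68e-05; Dhcr7 -1.29, Scd2 -1.28, Elovl6 -0.99 and Idi1 -0.83), smooth muscle markers 2 of 7 and 3 (0.0125), and ER-associated degradation 3 of 38 lower with 2 higher, and the same numbers adjusted over the list alone (0.0125). These 3 had adjusted p = 0.180, 0.127 and 0.561 with an estimated correlation. limma called 916 probe sets, 636 higher and 280 lower, but 518 (267 higher, 251 lower) with quantile normalization, 523 (261 and 262) with it within each set and 1084 (586 and 498) as planned. Without single arrays it called 461 (first untreated) and 540 and 311 (first and second treated).

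Between 4 h and 8 h in SS, inflammatory genes fell: Cxcl2 (-2.84 ± 0.63), Ccl7 (-2.83), Cxcl1 (-2.00), the NF-kB regulator Nfkbiz (-1.91) and Ccl2 (-1.83). The matricellular gene Ccn1 (-1.66), the growth factor gene Pdgfb (-1.63), Pdk4 (-1.88) and the histone genes H1f2 and H2bc1 (-1.69 and -1.66) were also lower. Rises were in Acbd6 (1.97), Tnnt2 (1.88), Reep6 (1.40), Cdsn (1.25), Itpr2 (1.201), Th (1.197), Surf2 (1.18), Madcam1 (1.15), Cad, an enzyme of pyrimidine synthesis (1.15), and Exosc5 (1.13). Atf4 (0.24 ± 0.15), Ddit3 (0.53 ± 0.25), Atf3 (-0.68 ± 0.35), Trib3 (0.33 ± 0.28), Asns (0.33 ± 0.19), Hspa5 (0.21 ± 0.17), Dnajb9 (0.10 ± 0.34), Herpud1 (-0.44 ± 0.28) and Eif2ak3 (-0.37 ± 0.58) did not pass the test between these times. NF-kB targets had 5 of 14 lower (7 adjusted over the list alone, camera adjusted p = 1.55e-08, adjusted p = 0.00132 with an estimated correlation), and fibroblast markers 1 of 10 (4 adjusted over the list alone, camera adjusted p = 0.000119, adjusted p = 0.0436 with an estimated correlation). Immediate early genes had 4 of 16 lower and 6 adjusted over the list alone (4.32e-08), and tRNA synthetases 3 of 16 higher and 12 (4.60e-09). Smooth muscle markers were lower as a list, with 0 of 7 called and 0 adjusted over the list alone (0.028). Lipid synthesis had 2 of 19 lower and 4 adjusted over the list alone (0.000827), and matrix genes 2 of 33 lower, or 5 lower and 1 higher adjusted over the list alone (0.000827). These 5 had adjusted p = 0.0881, 0.0881, 0.151, 0.371 and 0.0973 with an estimated correlation. limma called 163 probe sets, 115 higher and 48 lower, but the split turned with quantile normalization, to 23 (7 and 16). It was 6 (3 and 3) with quantile normalization within each set and 244 (129 and 115) as planned. The smaller pseudocount called 87, and leaving out each of the 4 arrays gave 11, 1, 18 and 1.

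In AA cells, which carry mutant eIF2alpha, limma called 0 probe sets at 4 h and 0 at 8 h, with 168 and 344 at an unadjusted p under 0.05. The planned filter called 4 and 13, no filter 4 and 15, the processing as planned 17 and 44, every other setting 0, and leaving out the first AA 8 h array 1 at 8 h. At 4 h Ddit3 was at 0.08 ± 0.25 (log2, SE), Atf4 at 0.20 ± 0.15, Atf3 at 0.14 ± 0.35, Trib3 at 0.02 ± 0.28, Asns at -0.11 ± 0.19, Hspa5 at 0.02 ± 0.17, Dnajb9 at 0.35 ± 0.34, Herpud1 at -0.05 ± 0.28 and Eif2ak3 at 0.17 ± 0.58. At 8 h these were -0.18, 0.23, -0.05, 0.06, -0.18, -0.26, -0.20, -0.35 and -0.02. Of the 26 gene lists, camera called 0 at either time.

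The difference of responses tested AA against SS directly. At 4 h the response was lower in AA for Fos (-4.03 ± 0.28, limma adjusted p = 1.75e-06; -0.41 by its other probe set), Atf3 (-3.02 ± 0.49), H1f2 (-2.76), Egr1 (-2.56 ± 0.33), Clk4 (-2.24), Grk5 (-2.22), Tab3 (-2.01), Hemgn (-1.97), Eno2 (-1.87) and Herpud1 (-1.87). The same held for Ddit3 (-1.77 ± 0.35, 0.0219) and Trib3 (-1.71 ± 0.40, 0.0492). It was higher for Kcnk2 (1.87), Trappc1 (1.81), Ak1 (1.74), Sparc (1.64 ± 0.27), Elovl6 (1.60), Prom1 (1.57), Itga3 (1.49; 0.38 by its other probe set), Nkain1 (1.48), Ccnf (1.45) and Fstl1 (1.43). Atf4 (-0.60 ± 0.22, 0.222), Dnajb9 (-1.02 ± 0.48), Hspa5 (-0.12 ± 0.24) and Eif2ak3 (-0.11 ± 0.82) did not pass. Asns did not pass by the probe set used here (-0.84 ± 0.27, 0.153) but did by its other one (-2.29 ± 0.38, 0.00636). With each of 8 arrays left out in turn, Atf3 stayed called in 8 cases, Ddit3 in 1, and Trib3 and Herpud1 in 0. Integrated stress response genes had 6 of 17 lower (14 adjusted over the list alone, median -1.16, camera adjusted p = 8.70e-15, adjusted p = 0.01 with an estimated correlation) and matrix genes 1 of 33 higher (8 adjusted over the list alone, camera adjusted p = 8.90e-07, adjusted p = 0.0305 with an estimated correlation). Immediate early genes had 3 of 16 lower and 4 adjusted over the list alone (3.01e-07), tRNA synthetases 0 of 16 and 4 (0.000507), interferon response genes 0 of 10 and 2 (0.00337), and amino acid synthesis 0 of 14 and 2 (0.0463). ER-associated degradation had 1 of 38 higher and 2 lower, or 2 and 2 adjusted over the list alone (median 0.24, 0.0171), and fibroblast markers 0 of 10 and 3 higher (0.0483). Those 6 had adjusted p = 0.114, 0.356, 0.356, 0.356, 0.467 and 0.315 with an estimated correlation. limma called 95 probe sets, 44 higher and 51 lower, 185 with the larger pseudocount, 168 with the Fv2E-PERK arrays alone, 212 with only these groups, 61 with quantile normalization within each set and 254 (148 and 106) as planned. Leaving out 1 array gave 62 and 45 (untreated SS), 25 and 33 (SS 4 h), 45 and 28 (untreated AA) and 24 and 35 (AA 4 h). Only without the first untreated SS array were more higher (36) than lower (26).

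At 8 h the AA response was lower for Ddit3 (-2.56 ± 0.35, limma adjusted p = 0.00143), Atf3 (-2.53; -1.55 and not called by its other probe set), Trib3 (-2.00), Herpud1 (-1.73), Asns (-1.24, and -3.09 by its other probe set) and Atf4 (-0.80 ± 0.22, 0.0442). With each of 8 arrays left out in turn, Ddit3 stayed called in 8 cases, Atf3 in 7, Trib3 and Asns in 4, Herpud1 in 3 and Atf4 in 1, and Atf4 was called in 7 of 15 settings. Lower responses were also found for B4galnt2 (-3.65), Gch1 (-3.14), Itpr2 (-2.75), Madcam1 (-2.52), Fbxo8 (-2.20), Reep6 (-2.16), Acbd6 (-2.11) and Fos (-2.71; the probe set of Fos with the highest mean gave 0.13). It was higher for Ccl7 (2.95), Rpl39l (2.64), Tgfbi (2.49), Nrp1 (2.41), Has2 (2.26), S100a4 (2.24), Ak1 (2.09), Col3a1 (2.03 ± 0.38), Sparc (1.82 ± 0.27) and Upk3b (1.81). The calls of B4galnt2 and Has2 were lost with any of the 8 arrays left out, and B4galnt2 was called in 8 of 15 settings. Dnajb9 (-1.67 ± 0.48, 0.0547, though its other probe set passed at -1.44), Hspa5 (-0.61 ± 0.24, 0.164) and Eif2ak3 (0.06 ± 0.82) did not pass. Integrated stress response genes had 12 of 17 lower (14 adjusted over the list alone, median -1.59, camera adjusted p = 3.46e-11, adjusted p = 0.0105 with an estimated correlation). Matrix genes had 9 of 33 higher (11 adjusted over the list alone, camera adjusted p = 1.01e-10, adjusted p = 0.00951 with an estimated correlation) and fibroblast markers 4 of 10 (5 adjusted over the list alone, camera adjusted p = 4.98e-06, adjusted p = 0.0105 with an estimated correlation). The tRNA synthetases had 10 of 16 lower and 14 adjusted over the list alone (6.28e-11), and amino acid synthesis 3 of 14 and 3 (0.0158). Lipid synthesis had 2 of 19 higher and 2 adjusted over the list alone (0.00372), and smooth muscle markers 0 of 7 and 2 (0.0226). These 4 had adjusted p = 0.0563, 0.244, 0.381 and 0.162 with an estimated correlation. limma called 394 probe sets, 90 higher and 304 lower, against 185 (71 and 114) with quantile normalization and 171 (64 and 107) with it within each set. It called 642 with the larger pseudocount, 647 with the Fv2E-PERK arrays alone and 652 (224 and 428) as planned. The count was 155 without the first untreated SS array, 256 and 93 without the first and second SS 8 h arrays, 110 and 198 without the first and second untreated AA arrays, and 119 without the second AA 8 h array.

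**Figure D2:**
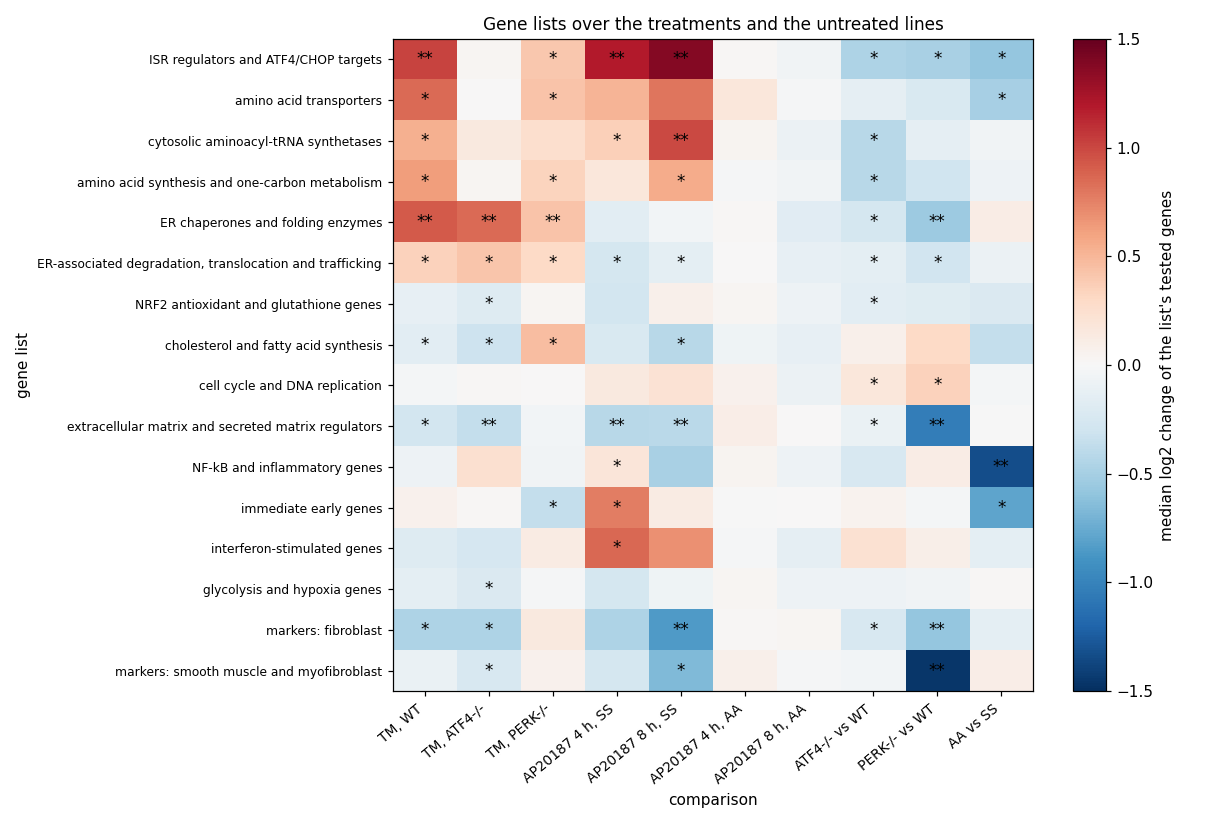
Median log2 change of 16 gene lists (vertical) in 10 comparisons (horizontal), as colour from -1.5 to 1.5, with * for a camera call at the preset correlation and ** for one that also held with an estimated correlation. The integrated stress response list had medians of 1.01 with tunicamycin in wild type and 1.38 in SS at 8 h. Differences of responses between lines are not drawn.

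How far tunicamycin and PERK activation changed the same genes was tested by overlap of calls from arrays they do not share. The calls came from 1 fit with a shared spread, so a probe set of small spread is more easily called in both. The lists are therefore not independent, and the exact tests may overstate the overlap. Probe sets were counted, and some genes, such as Dnajb9 and Wars, count more than once. 79 probe sets were higher both with tunicamycin in wild type and with AP20187 at 8 h in SS, against 13.03 expected of independent lists, and 18 were lower in both against 2.13 (two-sided Fisher's exact test, adjusted p = 2.79e-44 and 1.37e-12 over 6 tests). With AP20187 at 4 h, 49 were higher in both against 7.79 and 16 lower against 2.14 (exact test, adjusted p = 1.57e-26 and 1.74e-10). For ATF4-/- cells 27 were higher in both at 8 h against 5.61 (exact test, adjusted p = 1.37e-12), and for PERK-/- cells 1 against 0.604 (exact test, adjusted p = 0.469). With each set of arrays alone, where the spread is not shared, the 79 became 30 (5.96 expected). They became 24 as planned (2.79 expected), 48 with quantile normalization within each set (4.604 expected) and 0 with only the groups compared. Without the second SS 8 h, second untreated wild-type, second treated wild-type and first treated wild-type array, 47, 28, 34 and 48 were shared (3.33, 7.79, 5.36 and 6.54 expected).

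283 probe sets were higher with AP20187 at 8 h in SS and differed between SS and AA. Under tunicamycin their median log2 change was 0.31 in wild type, with 54 called higher, 0.24 in ATF4-/- with 19, and 0.03 in PERK-/- with 0. Against wild type, the median difference of responses was -0.35 in PERK-/-, where 206 of the 283 responded less and 6 were called lower, and -0.0012 in ATF4-/-, where 142 responded less and 1 was called lower. The 54 of these AP20187-induced probe sets called higher in wild type became 20 as planned, 22 with each set alone, 27 with quantile normalization within sets, 28 without the second AA 8 h array and 33 with quantile normalization. The 151 probe sets raised by tunicamycin in wild type had a median of 0.48 at 4 h and 0.71 at 8 h of AP20187 in SS, with 49 and 79 called higher. In AA their medians were 0.05 and -0.07 with 0 called at either time, and the difference from SS at 8 h was -0.72, with 54 called lower.

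**Figure D3:**
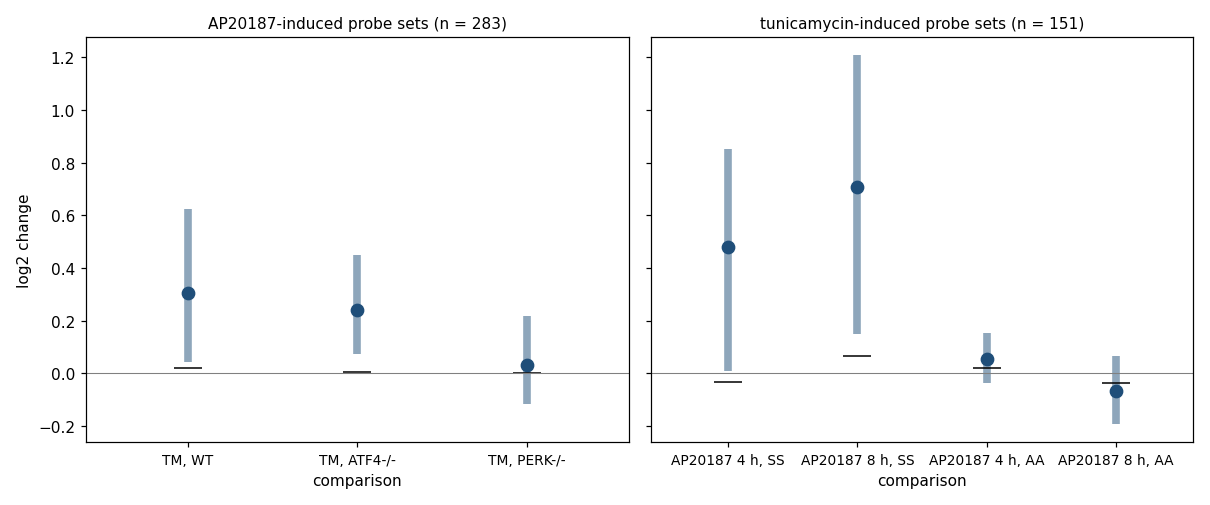
Log2 change of the 283 AP20187-induced and the 151 tunicamycin-induced probe sets in comparisons of other lines: median (points), 25th to 75th percentile (bars) and the median of all 7369 probe sets (black dashes). The AP20187-induced set had medians of 0.31, 0.24 and 0.03 with tunicamycin in wild type, ATF4-/- and PERK-/- cells.

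The untreated lines were compared to see what differed before any drug. In untreated ATF4-/- cells, Asns was lower than in wild type (-1.24 ± 0.19, log2; limma adjusted p = 0.0047). The growth factor binding protein gene Igfbp2 was lower (-3.13 ± 0.27), with Ogn (-3.13), Mep1b (-2.84), Anxa8 (-2.40), Ccn5 (-2.39), Aoc3 (-1.92), Serpinf1 (-1.85), Mc1r (-1.80), the antioxidant enzyme gene Nqo1 (-1.76) and the collagen crosslinking enzyme gene Lox (-1.64). The other probe sets of Serpinf1 and Lox gave -0.73 and -0.64 and were not called. Higher genes included the adhesion molecule gene Alcam (1.53 ± 0.16), Tnnt2 (1.55), Slc5a6 (1.42), Tes (1.33), Pvr (1.30), Plin2 (1.28), Sox11 (1.24), Aqr (1.23; 0.06 by its other probe set) and Myrf (1.13), and Rusc1 (1.82, though -0.47 by its most variable probe set). Ddit3 (-0.46 ± 0.25), Atf3 (-0.19 ± 0.35), Trib3 (-0.46 ± 0.28), Hspa5 (-0.44 ± 0.17), Dnajb9 (-0.67 ± 0.34), Herpud1 (-1.14 ± 0.28, 0.0807) and Eif2ak3 (0.64 ± 0.58, but 0.976-fold by group means) did not pass the test. Integrated stress response genes had 3 of 17 lower and 6 adjusted over the list alone (camera adjusted p = 5.96e-09): Atf4, Asns and Cebpb (-1.21). Atf4 is the disrupted gene, so its lower signal is no evidence of a pathway effect. The tRNA synthetases had 4 of 16 lower and 7 adjusted over the list alone (3.41e-07; Gars -0.80, Aars -0.75, Iars -0.65 and Lars -0.58), and amino acid synthesis 4 of 14 and 7 (3.47e-06; Aldh18a1 -1.18 and Psat1 -0.97). ER chaperones had 0 of 21 called and 0 adjusted over the list alone (0.000152), ER-associated degradation 0 of 38 and 1 lower (0.00657), fibroblast markers 0 of 10 and 1 lower (0.00657) and NRF2 targets 1 of 18 and 1 lower (0.0375). Matrix genes had 2 of 33 lower, or 4 lower and 1 higher adjusted over the list alone (0.0375), and cell cycle genes were higher with 0 of 35 called and 0 adjusted over the list alone (0.015). With an estimated correlation these 9 had adjusted p = 0.0668, 0.140, 0.0668, 0.140, 0.426, 0.140, 0.425, 0.383 and 0.425. limma called 64 probe sets, 23 higher and 41 lower, 119 with no filter or the planned filter, 99 with quantile normalization, 7 with the tunicamycin arrays alone and 0 with only these groups. Without the first and second ATF4-/- array it called 42 (9 higher, 33 lower) and 40 (7 and 33). Without the first wild-type array the split turned, with 72 called (45 higher, 27 lower), and without the second it was 50 (22 and 28).

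Untreated PERK-/- cells had lower expression of matrix genes than wild type. Of 33 matrix genes 20 were lower (23 adjusted over the list alone, median -1.04, camera adjusted p = 2.24e-22, adjusted p = 0.000253 with an estimated correlation), with Lox at -3.31, Col3a1 7.49-fold lower, Col1a2 at -2.23 and Col5a1 at -1.196. Smooth muscle markers had 4 of 7 lower (4 adjusted over the list alone, camera adjusted p = 1.94e-06, adjusted p = 0.00777 with an estimated correlation): Myl9 (-2.57), Cnn1 (-2.40), Acta2 (-1.76) and Tagln (-1.46). Fibroblast markers had 4 of 10 lower, or 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000313, adjusted p = 0.0379 with an estimated correlation). ER chaperones had 8 of 21 lower (10 adjusted over the list alone, camera adjusted p = 1.06e-08, adjusted p = 0.0227 with an estimated correlation), among them Hspa5 (-0.83 ± 0.17, limma adjusted p = 0.00994), P4hb (-1.52), Pdia6 (-1.09), Pdia5 (-0.998) and Hsp90b1 (-0.87), and Dnajb9 was lower by -1.32 ± 0.34. ER-associated degradation had 4 of 38 lower and 12 adjusted over the list alone (1.16e-05), integrated stress response genes 2 of 17 and 6 (0.000114; Vegfa -1.501 and Cebpb -0.79), and cell cycle genes 2 of 35 higher and 6 (8.57e-05; Ccnd1 1.05 and Kif11 0.69). These 3 had adjusted p = 0.229, 0.144 and 0.199 with an estimated correlation.

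Other large differences in untreated PERK-/- cells were lower Icam5 (-4.26 ± 0.83), Ccdc80 (-3.66), Mep1b (-3.36), Anxa8 (-3.28), Ccn5 (-2.95), Igfbp2 (-2.85) and Prss23 (-2.53). The cell cycle inhibitor gene Cdkn1c (1.99 ± 0.27) was higher, as were Orm3 (1.74), Aamdc (1.71), Mau2 (1.64), Slc5a6 (1.53), Adra2c (1.44) and Hmgb2 (1.41). Other probe sets did not bear out Ywhaq (2.81), Ppm1b (1.54; -0.0017 by another rule) or Rusc1 (1.52; -0.49). Atf4 (-0.48 ± 0.15, limma adjusted p = 0.0868), Ddit3 (-0.21 ± 0.25), Atf3 (-0.13 ± 0.35), Trib3 (-0.53 ± 0.28), Asns (-0.57 ± 0.19), Herpud1 (-0.59 ± 0.28) and Eif2ak3 (-0.44 ± 0.58) did not pass. limma called 368 probe sets, 122 higher and 246 lower, but 122 (26 higher) with the tunicamycin arrays alone, 233 as planned, 603 with quantile normalization and 2 (both lower) with only these groups. Both knockouts were set against the same wild-type arrays, so the overlap of their lists was not examined.

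Untreated AA and SS cells differed in 1086 probe sets by limma, 432 higher and 654 lower in AA, against 916 for the largest treatment response. Podoplanin (Pdpn) was lower in AA (-6.27 ± 0.76, log2), as was Cyba, an NADPH oxidase subunit gene (-3.81). Wnt10a (-3.50), Ccl7 (-3.50), the aryl hydrocarbon receptor gene Ahr (-3.29), Dusp6 (-3.26; -0.05 by its other probe set), Gfpt2 (-3.26), Mfap2 (-3.25), Pon3 (-3.19) and Myb (-3.17) were also lower. Mab21l2 (3.45 ± 0.30), Dkk3, a secreted Wnt pathway protein gene (3.26), 2210016F16Rik (2.83), Cap1 (2.82), Snhg6 (2.80), Gatm (2.66), Slc1a6 (2.61), Chst2 (2.56), Foxd1 (2.56) and Hspa1b (2.48) were higher. Atf4 (-0.64 ± 0.15, adjusted p = 0.0111 by limma), Atf3 (-1.44 ± 0.35, 0.0105) and Trib3 (-0.88 ± 0.28, 0.0493) were lower in AA, but the other probe set of Atf3 did not pass (-0.47 ± 0.33, 0.401). With each of the 4 arrays left out in turn, Atf4 stayed called in 2, Atf3 in 1 and Trib3 in 0 cases. Ddit3 (0.39 ± 0.25), Asns (-0.02 ± 0.19), Hspa5 (-0.03 ± 0.17), Dnajb9 (0.21 ± 0.34), Herpud1 (-0.37 ± 0.28) and Eif2ak3 (0.93 ± 0.58) did not pass. NF-kB targets had 9 of 14 lower (9 adjusted over the list alone, median -1.33, camera adjusted p = 1.50e-06, adjusted p = 0.00372 with an estimated correlation), with Ccl2 (-2.93), Nfkbia (-1.75) and Nfkb2 (-1.54). Immediate early genes had 9 of 16 lower and 9 adjusted over the list alone (1.36e-05; Ier3 -1.70, Ier2 -1.58 and Myc -1.51), integrated stress response genes 7 of 17 lower with 1 higher, and 8 and 1 (0.0107; Vegfa -2.35 and Ndrg1 -1.72), and transporters 1 of 7 and 1 lower (0.0107; Slc38a4 -2.98). With an estimated correlation these 3 had adjusted p = 0.224, 0.529 and 0.224. The processing as planned called 2126 probe sets, and leaving out 1 array gave 695 and 677 (first and second SS) and 594 and 462 (first and second AA).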

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

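The genes and lists given first are differences between the responses of 2 lines to the same treatment that passed limma's interaction test or, for a gene list, camera with both the preset and the estimated correlation. The 3 patterns weighed after them were not held to that rule. Of the tests of these patterns, the fit without the second AA 8 h array, the count of differences between the untreated SS and AA lines and the leukocyte markers were chosen only after the result was seen.

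The responses of ATF4-/- and wild-type cells to tunicamycin differed for 4 probe sets, with log2 differences of 2.60 for Gadd45b, 2.26 for Mc1r and -2.10 for St3gal3, and a median of -0.87 over the integrated stress response list. That list includes Atf4, the disrupted gene, whose own difference is the median. The 4 probe sets do not exceed what unchanged data gave in simulations (2 on average and up to 8), and the tunicamycin arrays alone called 0. The planned filter called 37, where unchanged data gave 10.8 on average and up to 20. The responses of PERK-/- and wild-type cells differed for 34, but for 0 with the tunicamycin arrays alone, where 0 of the 19 genes named next stayed called, and 18.5% of simulated calls were false. They were higher in PERK-/- for Mep1b (3.96), Mc1r (2.88), Dhcr7 (2.42), Gpr162 (1.91), Hspa1b (1.82), Idi1 (1.64), Itgav (1.57), Nudcd3 (1.49) and Scd2 (1.49). They were lower for Ddit3 (-3.24), Tnnt2 (-2.37), Atf6 (-2.26), Siah2 (-2.21), Hoxa4 (-2.20), Myc (-1.94), Creld2 (-1.80), Rbpj (-1.62), Gnpnat1 (-1.58) and Stbd1 (-1.52).

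The 4 h responses of AA and SS to AP20187 differed for 95 probe sets, with list medians of -1.16 for integrated stress response genes and 0.54 for matrix genes. Differences above 0 were those of Kcnk2 (1.87), Trappc1 (1.81), Ak1 (1.74), Sparc (1.64), Elovl6 (1.60), Prom1 (1.57), Itga3 (1.49), Nkain1 (1.48), Ccnf (1.45) and Fstl1 (1.43). Differences below 0 were those of Fos (-4.03), Atf3 (-3.02), H1f2 (-2.76), Egr1 (-2.56), Clk4 (-2.24), Grk5 (-2.22), Tab3 (-2.01), Hemgn (-1.97), Eno2 (-1.87), Herpud1 (-1.87), Ddit3 (-1.77) and Trib3 (-1.71). At 8 h they differed for 394, with medians of -1.59 for integrated stress response genes, 0.55 for matrix genes and 0.94 for fibroblast markers. Positive differences were those of Ccl7 (2.95), Rpl39l (2.64), Tgfbi (2.49), Nrp1 (2.41), Has2 (2.26), S100a4 (2.24), Ak1 (2.09), Col3a1 (2.03), Sparc (1.82) and Upk3b (1.81). Negative ones were those of B4galnt2 (-3.65), Gch1 (-3.14), Itpr2 (-2.75), Fos (-2.71), Ddit3 (-2.56), Atf3 (-2.53), Madcam1 (-2.52), Fbxo8 (-2.20), Reep6 (-2.16), Acbd6 (-2.11), Trib3 (-2.00), Herpud1 (-1.73), Asns (-1.24) and Atf4 (-0.80).

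The first pattern is that AP20187 called 0 probe sets in AA by limma (168 at 4 h and 344 at 8 h at an unadjusted p under 0.05). The 0 rests on the floor filter, which was chosen after counts had been seen. The planned filter called 4 at 4 h and 13 at 8 h, and the processing as planned 17 and 44. With no change simulated, the planned filter gave at most 5 calls at 4 h and 6 at 8 h. A wider spread between the AA replicates would leave the size of the response in place, but the 636 probe sets higher in SS at 8 h had a median of -0.10 in AA against 0.85 in SS, with quartiles of -0.22 and 0.02, which argues against it. The second AA 8 h array, from the pair with the lowest correlation, is argued against as well. Leaving that array out brought no calls at 8 h, though such a fit keeps 1 array in the group. At 4 h, where that array is not among those compared, 0 were called too. What stays open is another difference between the lines than the eIF2alpha mutation: 1086 probe sets differed between untreated AA and SS, the labels state a PERK-/- background for SS only, and with 1 line per genotype the mutation and the line cannot be told apart.

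The second pattern is that lipid synthesis genes responded differently to tunicamycin in PERK-/- and wild type, with a median difference of 0.60 (camera adjusted p = 5.65e-10, but adjusted p = 0.0658 with an estimated correlation). In wild type 3 of 19 were called lower, and in PERK-/- 0 were called. The list calls in these lines were also lost with an estimated correlation (adjusted p = 0.341 and 0.0907). An array-wide shift between the groups is argued against by a median of 0.55 after quantile normalization, with 19 of 19 members above 0. A lower untreated level in PERK-/- is argued against as well, since the list was at 0.30 there relative to untreated wild type, with 15 of 19 higher. The unstated duration of tunicamycin in PERK-/- cells and a role of PERK itself both stay open and were not tested. Each genotype is a single line, and 368 probe sets differed between untreated PERK-/- and wild type. The knockout and the line can therefore not be told apart.

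The third pattern is that inflammatory genes were higher in untreated SS than in AA, with a list median of -1.33 for AA minus SS. A single untreated array that stands apart is argued against, because leaving out each of the 4 gave medians from -1.42 to -1.28. RNA of leukocytes in the SS cultures is left open: 4 of the macrophage and leukocyte markers were tested, with a median of -0.15 and 1 of them higher in AA, too few to decide. Basal activity of Fv2E-PERK in SS was not tested and stays open.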

How the results depend on the processing

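The processing as planned, the planned filter, each set of arrays fitted alone, quantile normalization within each set, the fit without the second AA 8 h array and the probe set with the highest mean were tried only after the data had been seen. Arrays carry no depth, no signal over background was given, and 2 arrays per group limit the precision. Of 354 named-gene results, limma left the side of the threshold unchanged, with no called direction turned, in 325 with a 4-fold smaller and 334 with a 4-fold larger pseudocount, 352 without the trend, 306 with quantile normalization, 278 with the processing as planned, 267 with each set of arrays alone and 227 with only the groups compared, and 344 of 344 with the filter at the 75th percentile. Among the unchanged, results that passed under neither setting turned sign in 1, 4, 0, 8, 6, 0, 0 and 0 cases, in that order. Of 390 gene list results these numbers were 384, 379, 389, 369, 363, 381, 377 and 371, and 0 of the lists called here turned direction under any setting. With an estimated correlation the 92 list calls became 24. For results whose count moved by over 1.5 times the cause was not tested, except where fewer samples entered the fit.

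Quantile normalization moved the count for tunicamycin in ATF4-/- to 200 and in PERK-/- to 33, for ATF4-/- minus wild type to 7, for SS at 8 h to 518 and 8 h against 4 h to 23, for AA minus SS at 8 h to 185, for untreated ATF4-/- to 99 and untreated PERK-/- to 603, and the AP20187-induced probe sets called higher in wild type from 54 to 33. Quantile normalization within each set gave 181 for ATF4-/-, 9 for PERK-/-, 7 for ATF4-/- minus wild type, 523 and 6 for SS at 8 h and 8 h against 4 h, 61 and 171 for AA minus SS at 4 h and 8 h, 48 shared probe sets, 27 AP20187-induced ones and 48 tunicamycin-induced ones called in SS at 8 h. The smaller pseudocount gave 40 for PERK-/- and 87 for 8 h against 4 h, and the larger 7 for ATF4-/- minus wild type, 341 for 8 h against 4 h, and 185 and 642 for AA minus SS. Without the trend, ATF4-/- minus wild type gave 8. No filter and the planned filter gave 69 each for PERK-/-, 36 and 37 for ATF4-/- minus wild type, 57 each for PERK-/- minus wild type, 4 each in AA at 4 h, 15 and 13 in AA at 8 h, and 119 each for untreated ATF4-/-.

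The processing as planned gave 86 for wild type, 10 for PERK-/-, 9 for ATF4-/- minus wild type, 1007 for SS at 4 h, 17 and 44 for AA, 254 and 652 for AA minus SS, 233 for untreated PERK-/-, 2126 for untreated AA against SS, 24 shared, 20 AP20187-induced and 24 tunicamycin-induced. Each set of arrays alone gave 62, 31 and 0 for tunicamycin in wild type, ATF4-/- and PERK-/-, 0 and 0 for their differences, 303 for 8 h against 4 h, 168 and 647 for AA minus SS, 7 and 122 for untreated ATF4-/- and PERK-/-, 30 shared, 22 AP20187-induced and 30 tunicamycin-induced. With only the groups of the contrast, which leaves 2 to 4 residual degrees of freedom, all 3 tunicamycin responses and both differences gave 0 (at an unadjusted p under 0.05 the main counts were 991, 879, 697, 510 and 766), untreated ATF4-/- 0, untreated PERK-/- 2, 8 h against 4 h 413, AA minus SS at 4 h 212, shared probe sets 0 and AP20187-induced ones 0; the tunicamycin-induced set was then empty and gave no value. The fit without the second AA 8 h array gave 119 for AA minus SS at 8 h and 28 AP20187-induced.

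The probe set with the highest mean turned Arih1 in PERK-/- to -0.14, Fos in AA minus SS at 8 h to 0.13 and Ppm1b in untreated PERK-/- to -0.0017. That with the highest variance turned Arih1 to -0.14, Ppm1b to -0.0017, Tm4sf1 in PERK-/- to 0.044, and Rusc1 to -0.47 in untreated ATF4-/- and -0.49 in untreated PERK-/-.

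With the replicate number as a replicate block, the count was 30 for PERK-/-, 59 for PERK-/- minus wild type, 335 for 8 h against 4 h, and 163 and 673 for AA minus SS, with the other counts within 1.5 times. The numbers do not pair the samples: within a line, deviations of arrays with the same number correlated at -0.0164 to 0.127.

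Leaving out 1 array at a time, where the lone array left is assumed to vary like the other groups, gave 117 to 176 calls for wild type, 37 to 64 for ATF4-/-, 20 to 89 for PERK-/-, 2 to 22 and 16 to 72 for their differences from wild type, 182 to 465 for SS at 4 h, 311 to 622 at 8 h, 1 to 18 for 8 h against 4 h, 0 to 0 and 0 to 1 for AA, 24 to 62 and 93 to 572 for AA minus SS, 40 to 72, 259 to 359 and 462 to 695 for the untreated comparisons, 28 to 77 shared, 20 to 68 AP20187-induced and 28 to 77 tunicamycin-induced. Of 1788 named-gene results with an array left out, 1291 stayed on their side of the threshold, 485 lost it, 12 gained it and 0 turned direction while called.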

Other observations

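Ppp1r15a, which encodes the phosphatase subunit GADD34 that reverses eIF2alpha phosphorylation, was left out by the floor filter, being at the floor on 1 array. With the planned filter it rose by 3.88 ± 0.31 (log2, SE) with tunicamycin in wild type (limma adjusted p = 1.05e-05). The difference from wild type was -3.53 ± 0.43 in ATF4-/- and -3.44 ± 0.43 in PERK-/- (limma adjusted p = 0.00241 and 0.00216). AA minus SS was -2.38 at 4 h and -2.705 at 8 h (limma adjusted p = 0.0238 and 0.00606). The floor value of Ppp1r15a lay on an untreated wild-type array, so its wild-type changes are rough. Its ratios went from 0.01 and 0.330 in untreated to 5.49 and 5.35 in tunicamycin-treated wild-type cells. They went from 0.415 and 0.521 to 0.765 and 0.575 in ATF4-/- cells, and from 0.412 and 0.301 to 0.806 and 0.388 in PERK-/- cells. In SS the ratios were 1.49 and 1.19 untreated, 7.02 and 7.41 at 4 h, and 9.74 and 10.7 at 8 h, and in AA all 6 lay between 0.793 and 1.11.

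10 of the 26 gene lists were called in 0 of the 15 comparisons by camera. The lowest adjusted p over the comparisons was 0.0552 for the 12 tested p53 targets, 0.0665 for 22 heat shock proteins and 0.109 for 17 ribosomal proteins. Among markers of other cell types it was 0.0865 for skeletal muscle (5 tested), 0.0865 for neural cells (6), 0.0931 for macrophages and leukocytes (4), 0.182 for epithelium (3), 0.202 for bone and cartilage (3), 0.204 for endothelium (3) and 0.230 for adipocytes (5).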
